A study of Mus musculus with 1666 samples.

How the data were processed

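The series holds single-cell RamDA-seq profiles of mouse whisker follicle cells from 7 embryonic stages, sorted 1 cell per well. The deposited table gives TPM, abundance scaled for gene length and library size, for each cell, which the authors had summed over the genes that share a symbol, and columns total 991213 to 999516. Per the submitters' processing notes, bcl2fastq 1.0, HISAT2 2.0.4 and featureCounts of Subread 1.5.0 were used with the mm10 build; the annotation release is not stated. Of 1666 labelled cells, the 52 marked as low quality have no column, and the other 1614 were all used (unused columns: 0). Each column was joined to its label by its name. The table holds 49662 symbols, of which 49472 are above 0 in some cell and 21290 matched a protein-coding gene of GENCODE M21, the annotation used here for gene types and positions. No 2 cells have identical columns. Krt85, a member of the matrix list, is not in the table. Raw reads were not used here.

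TPM keeps no depth, so cells could not be thinned to a common depth, and the number of genes at 1 TPM or more per cell is given instead, with stage medians from 16601 to 19468.5. A single microRNA locus, Mir6236, which lies over ribosomal RNA sequence, took 17.9 to 23.3% of TPM by stage. Protein-coding symbols took 37.9 to 41.6%. Mitochondrial, ribosomal RNA and 7SK/7SL symbols, with Mir6236 not counted among them, took 7.49 to 9.13%. Rescaling each cell to protein-coding genes shifts the median of all genes by 1.20 to 1.32 on the log2 scale in every stage. Between E17.0 and E12.0 this shift is -0.06. Removing the mitochondrial, ribosomal RNA and 7SK/7SL symbols, with Mir6236 kept, shifts the median by 0.10 to 0.12, and median-of-ratios factors by -0.14 to 0.08. All changes are thus relative to the TPM total.

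Stage means were made by averaging TPM over the cells of a plate and then over the plates of a stage with equal weight. The labels name no embryo, litter or culture, so a stage is 1 sample, the 7 stages are the units of every test, and plates were not used as replicates. Trends were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend) on log2 of the stage mean plus a pseudocount of 1 TPM, for genes with a mean of at least 1 TPM over the stages. Embryonic day was the covariate, a quadratic term was added for curvature, tests were two-sided, and the threshold was a Benjamini-Hochberg adjusted p of 0.05. Gene lists (20 of programs and sample quality, 9 of other cell types) were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives, and adjusted over the 20 lists. List scores, the mean over members of log2(stage mean TPM + 1), were related to day with Pearson's r and Spearman's rho and exact permutation tests.

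Co-expression with Sox9, Shh and Lrig1 was measured within each plate as the partial Spearman correlation over cells, given the number of genes detected per cell. Plates entered where the gene was at 1 TPM or more in at least 5 cells, and genes where they were at 1 TPM or more in at least 10% of cells. Fisher z values were averaged over the plates of a stage with weights of the cell number less 4, and their mean over stages was tested with a one-sample limma fit. Folds between stages and shares of cells have no test; shares carry exact Clopper-Pearson 95% intervals. The limit for a count of 0 is 3 cells of the total. For other calculations Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

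Genes are named by a rule. For trend and curvature these are the 12 steepest each way among genes past the test with a highest stage mean of at least 20 TPM. For E17.0 against E12.0 they are the 8 largest folds each way, and for neighbouring stages the 4 largest, among genes with plate ranges that do not overlap and a higher mean of at least 20 TPM. For co-expression they are the 10 largest mean z each way past the test. Predicted genes, ribosomal protein, mitochondrial and small RNA symbols and pseudogenes were passed over, and list members, Sox9, Shh, Lrig1 and Xist may also be named. The tests, lists, naming rule and most alternatives were chosen before the data were examined. The class rules, every fit in epithelial-like cells and the test of the difference between the Shh and Sox9 correlations were added after the mixture of cell types was seen. No doublet caller was run, since the cells were sorted into single wells, and cells that carry basal and fibroblast markers together were left in neither class.

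Alternatives were other pseudocounts (0.1 and 5 TPM), a filter at 10 TPM and none, the mean of log2 values and cells pooled without plate weights. Those of scaling were protein-coding genes rescaled, removal of mitochondrial, ribosomal RNA and 7SK/7SL symbols with Mir6236 kept, and median-of-ratios scaling. Further ones were the rank of the stage in place of its day, other correlation measures and terms, and leaving out each stage and each plate. Both analyses were tested on simulated data. In the trend test, made with normal noise of each gene's residual spread, 18, 38, 46 and 50 of 50 genes with slopes of 0.25, 0.5, 1 and 2 log2 per day were found in epithelial-like cells, with 5 false calls among 23496 other genes. Over all cells 16, 35, 47 and 50 of 50 were found, with 7 false calls among 24314. For co-expression with Sox9, each gene was shuffled among the cells of a plate. The same correlation was then planted in every plate, in widely detected genes only. At correlations of 0.1, 0.2, 0.3 and 0.5, 7, 43, 50 and 50 of 50 genes were found, with 0 false calls among 27872. Links between genes and differences between stages were thus left out, so these counts hold for that setting only.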

Results

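Single cells of mouse whisker follicles were profiled by RamDA-seq, a full-length total RNA method, at 7 embryonic stages from E11.5 to E17.0. The labels name 1666 cells, of which 52 were marked as low quality and had no values, and 1614 cells on 18 library plates were analysed. These were 94 cells at E11.5, 276 at E12.0, 267 at E13.0, 181 at E13.5, 177 at E14.0, 350 at E15.0 and 269 at E17.0. Cells had been sorted for ITGA6, the alpha 6 integrin of basal epidermis, and against CD31, an endothelial surface protein. From E12.0 on they also carried the red form of a photoconvertible protein that had been switched by light in whole whisker follicles, a step that the E11.5 cells lacked. The labels name no embryo or litter, so each stage counted as 1 sample without a labelled biological replicate, and whether the plates of a stage come from the same embryos is not known. Depth per cell is unknown because the values are TPM. The median number of genes at 1 TPM or more ranged from 16601 per cell at E17.0 to 19468.5 at E12.0.

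The first question was which kinds of cell the gate had delivered at each stage. Epithelial cells carrying Krt5, a basal keratin, made up most of the cells, and the second large group expressed Col1a1 and Col3a1, the fibrillar collagens of mesenchyme. Cells with 7 or more of 12 basal epidermis markers at 10 TPM or more and under 3 of 8 fibroblast markers are called epithelial-like here, a rule set after the values were seen from marker lists fixed before. They were 1006 of the 1614 cells (62.3%), with a median of 488 TPM for Krt5 and 0.163 TPM for Col1a1. Fibroblast-like cells, with 3 or more fibroblast markers and under 7 basal markers, were 439 cells (27.2%), with medians of 937 TPM for Col1a1, 1592 TPM for Col3a1 and 0 TPM for Krt5. These markers define the groups, so their levels are no independent evidence of the cell type. The remaining 169 cells (10.5%) met neither rule. Among them 48 had 3 or more nerve and Schwann cell markers, 45 had endothelial, 14 melanocyte, 14 fibroblast, 10 Merkel cell and 10 immune markers, and 36 had none of the marker sets tested.

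The mix differed between stages. At E12.0, 97.1% of 276 cells were epithelial-like (exact binomial 95% interval 94.4 to 98.7%) and 0 were fibroblast-like, which allows a share of up to 1.09%. At E13.0, 80.1% of 267 cells were fibroblast-like (74.9 to 84.8%), with 73.3, 82.4 and 84.4% on its 3 plates, and 53 epithelial-like cells were left. Dermal papilla markers, those of the mesenchymal condensate under the follicle, were present in 159 of the 267 E13.0 cells. Epithelial-like cells were 85.1% at E13.5, 77.4% at E14.0, 49.4% at E15.0 and 61.3% at E17.0. E15.0 plate 1 stood apart, with 10% epithelial-like and 82.2% fibroblast-like cells, against 20.5 to 26.7% fibroblast-like cells on the other 3 plates of that stage. At E11.5, 18.1% of 94 cells carried nerve and Schwann cell markers, and at E17.0 endothelial markers were present in 7.06% of cells although the gate excluded CD31. All intervals and limits for shares of cells cover counting error only.

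**Figure D1:**
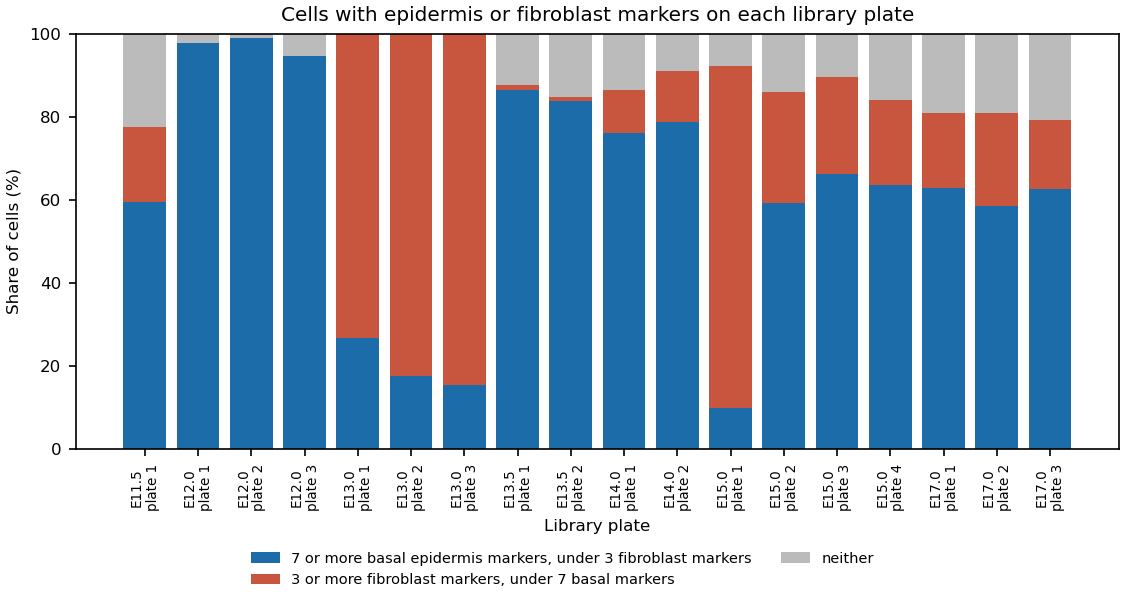
Share of cells (%) that were epithelial-like, fibroblast-like or neither, with 1 bar per library plate, grouped by embryonic stage. The 3 E13.0 plates and E15.0 plate 1 hold 73.3 to 84.4% fibroblast-like cells, and the E12.0 plates hold 94.6 to 98.9% epithelial-like cells.

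Xist, the RNA that coats the inactive X chromosome of female cells, was at 1 TPM or more in 37.8 to 58.1% of cells on the plates of E11.5, E12.0, E13.0 and E15.0 plates 2 to 4. On the plates of E13.5, E14.0 and E17.0 and on E15.0 plate 1 it was found in 2.22 to 7.69% of cells. The sex mix thus differed between stages, and E15.0 plate 1 had another mix than the other plates of its stage. Mean Xist was 109 TPM in epithelial-like cells of E12.0 and 0.491 TPM at E17.0. For each plate, the plate with the most similar mean profile came from the same stage for 16 of the 17 plates that share their stage with another over all cells, and for 17 of 17 over epithelial-like cells. The exception over all cells was E15.0 plate 1, closest to E13.0 plate 1. The nearest plate shared the description format, the form of the description text, for 13 and 11 of 18 plates. No label says whether this format marks a sequencing batch.

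The second question was which genes rise or fall with embryonic day over the 7 stages. Averaged over all cells, the largest folds between E12.0 and E17.0 included collagens of fibroblast-like cells, of which E12.0 had 0, and genes such as Krt17 and Foxi3 with folds of similar size in epithelial-like cells. Col1a1 was at 2.64 TPM at E12.0 and 499 TPM at E17.0 (log2 fold 7.10), and Col3a1 was at 3.75 and 616 TPM (7.02). Krt17, a keratin of the follicle's outer root sheath and companion layer, was at 6.74 and 527 TPM (6.09), and Dct, a pigment enzyme of melanocytes, was at 0.0493 and 47.9 TPM (5.54). Foxi3, a transcription factor of hair placodes, was at 28.5 and 0.326 TPM (-4.48), Wnt3, a Wnt ligand, at 23.8 and 1.08 TPM (-3.58), and Hmga2, a chromatin protein of fetal growth, at 157 and 12.7 TPM (-3.53). Among genes whose plate ranges did not overlap, Ccer2 (6.37, but 4.36 without E17.0 plate 3), Ccl2, Col6a3 and Lmcd1 were the others with the largest folds toward E17.0, and Xist, Itgam, Pygm, Susd4 and Mpped1 the others with the largest folds toward E12.0. These folds compare 1 sample with 1 sample and carry no test. In the limma fit over the 7 stages, 0 of 24514 genes passed an adjusted p of 0.05 for a linear trend (3777 at an unadjusted p under 0.05), and 0 passed for a curved course (1938 unadjusted). Leaving out E17.0 plate 2 or plate 3 gave 62 calls each, leaving out E13.0 gave 26, E15.0 plate 1 gave 20, E14.0 plate 2 gave 19, E17.0 plate 1 gave 11, E13.5 plate 2 gave 8, E13.0 plate 2 gave 6 and E15.0 plate 4 gave 1. The 0 calls also depend on the scale, with 434 for the rank of the stage in place of its day, 70 for a pseudocount of 5 TPM, 30 for protein-coding genes rescaled and 13 for the mean of log2 values.

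Steps between neighbouring stages over all cells were led by genes of mesenchyme in several cases. From E12.0 to E13.0, Col3a1 went from 3.75 to 1166 TPM (log2 fold 7.94) and Prrx1, a mesenchymal homeobox gene, from 0.388 to 153 TPM (6.80), while Wnt7b went from 49.1 to 2.64 TPM (-3.78). From E13.0 to E13.5, Twist2, a regulator of dermal fibroblasts, went from 139 to 0.277 TPM (-6.78) and Cdh5, the cadherin of endothelial cells, from 0.0763 to 40.4 TPM (5.27). From E11.5 to E12.0, Npy, a neuropeptide, went from 43.8 to 0.186 TPM (-5.24) and Twist1 from 45.6 to 0.483 TPM (-4.97), and Lhx2, a LIM homeobox gene of hair placodes and stem cells, went from 0.361 to 47.1 TPM (5.14). From E14.0 to E15.0, Tbx15, a T-box gene of dermis, went from 2.55 to 40.7 TPM (3.55), or to 7.79 TPM (1.31) without E15.0 plate 1, and Krt79, a keratin of the upper follicle duct, went from 94.8 to 10.99 TPM (-3.00). No test applies to these steps.

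Within epithelial-like cells, a selection added after the cell mix was seen, 503 of 23696 genes had a linear trend in the limma fit, 328 rising and 175 falling (4479 at an unadjusted p under 0.05). The 12 steepest rises included Vdr and Tbx1 of the hair follicle stem cell list and Krt28 of the inner root sheath list. Lmcd1, a GATA-binding cofactor, rose by 1.26 log2 per day (SE 0.18; n = 7 stages; limma adjusted p = 0.0202), from 0 TPM at E11.5 to 73.8 TPM at E17.0. Vdr, the vitamin D receptor needed for hair cycling, rose by 1.02 log2 per day (SE 0.15; adjusted p = 0.0243), from 4.01 to 129 TPM. Tbx1, a T-box factor of hair follicle stem cells, rose by 0.98 log2 per day (SE 0.19; adjusted p = 0.0462), from 0.024 to 46.04 TPM, and Krt28, an inner root sheath keratin, by 0.95 (SE 0.14; adjusted p = 0.0211), from 0.009 to 24.8 TPM. Cd44, the hyaluronan receptor, went from 2.29 to 117 TPM, and Neat1, the scaffold RNA of nuclear paraspeckles, from 2.27 to 212 TPM. S100a14, Hspa4l, Ndufa4l2, Itga1, Col1a2 and Igfbp7 completed the 12, with slopes from 0.92 to 1.17 log2 per day. Col1a2 is a fibroblast marker and rose from 2.37 to 74.3 TPM in cells chosen for few such markers.

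The 12 steepest falls included Igf2 and Mest of the heterochronic and fetal growth list. Rimklb, an amino acid ligase, fell by 0.95 log2 per day (slope -0.95; SE 0.064; adjusted p = 0.00589), from 69.1 to 0.975 TPM. Igf2, the imprinted fetal growth factor, had a slope of -0.84 log2 per day (SE 0.11; adjusted p = 0.0175), from 626 to 19.2 TPM. Grb10, an imprinted growth-limiting adaptor, had a slope of -0.77 (SE 0.046; adjusted p = 0.00589), from 299 to 17.4 TPM. Mest, an imprinted hydrolase gene, went from 389 to 42.2 TPM, Cdkn1c, an imprinted cell cycle inhibitor, from 99.4 to 9.72 TPM, and Mdk, the growth factor midkine, from 390 to 40.4 TPM. Lmx1b, a LIM homeobox gene, went from 40.9 to 0.282 TPM, and Cldn6, a tight junction protein of embryonic epithelia, from 49.2 to 1.60 TPM. Mpped1, Susd4, B3gnt5 and Crnde were the other falls among the 12, with slopes from -0.74 to -0.58 log2 per day. For a curved course, 1 gene passed in the limma fit (2984 at an unadjusted p under 0.05): Calm4, a calcium-binding protein of differentiating epidermis, named after its values were seen, at 0.13 TPM at E11.5, 13.04 TPM at E14.0 and 2.34 TPM at E17.0 (adjusted p = 0.0270).

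**Figure D2:**
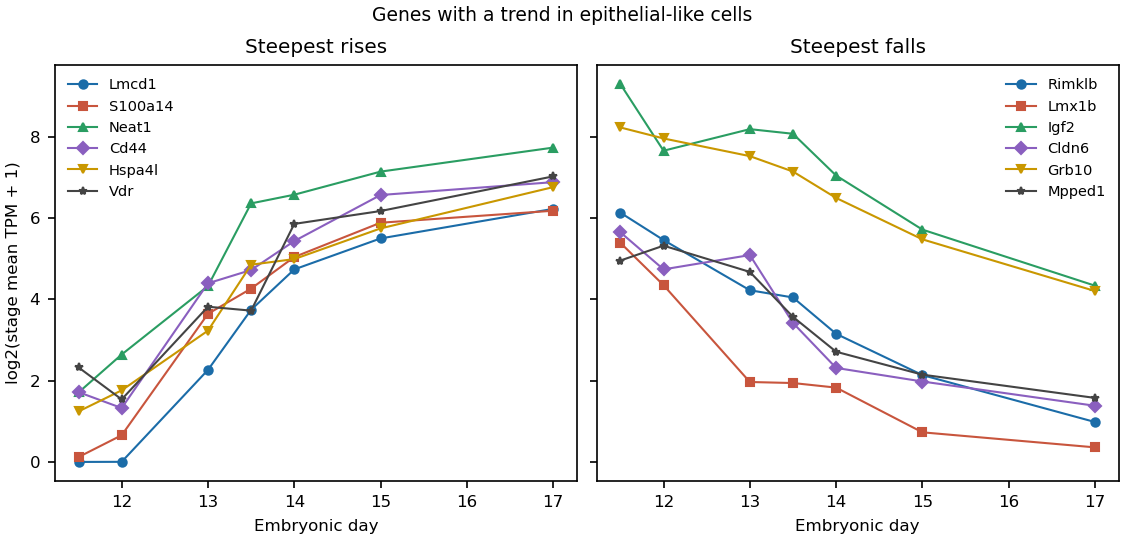
The log2 of the stage mean TPM plus 1 against embryonic day in epithelial-like cells, for 6 of the named genes with a rising and 6 with a falling linear trend; each point is 1 stage (n = 1 sample, no error shown). Vdr reaches 129 TPM and Cd44 117 TPM at E17.0, while Igf2 drops to 19.2 TPM and Grb10 to 17.4 TPM.

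The count of 503 rests on each of several stages. It was 44 without E15.0, 111 without E11.5, 194 without E12.0, 280 without E14.0, 290 without E13.5 and 321 without E13.0. Without E17.0 it was 406, of which only 177 were among the 503. All of the 24 named genes kept the sign of their slope whichever stage was left out, and from 5 of them (without E15.0) to 17 (without E17.0) still passed. The split into 328 rising and 175 falling genes became 351 rising and 401 falling when log2 values were averaged over cells, with 427 genes shared. With the rank of the stage in place of its day, 776 genes rose and 665 fell, 479 of them among the 503. In the 8 plates of the lane format, which cover 5 stages, 100% of the 503 genes had a slope of the same sign, with a median size of 0.45 log2 per day against 0.39 over all plates. These plates were part of the fit that chose the genes. In the 691 epithelial-like cells with Xist under 1 TPM, 396 genes passed, of which 375 were among the 503.

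Gene lists for programs of the follicle and skin, fixed beforehand, were then tested in epithelial-like cells with camera, limma's test of a list against all other genes. Hair follicle stem cell genes rose as a list (adjusted p = 5.09e-05; 0.0809 as an adjusted p with an estimated correlation). Of 16 members tested, 2 rose over all genes, Vdr and Tbx1, and 7 rose and 1 fell when adjusted over the list alone. Sox9, the stem cell regulator, was at 2.42 TPM at E11.5 and 71.3 TPM at E17.0 (adjusted p = 0.183), Nfatc1, which keeps bulge stem cells quiescent, at 0.091 and 223 TPM (adjusted p = 0.0821), and Krt15, a bulge keratin, at 44.5 and 563 TPM. Inner root sheath genes rose as a list (adjusted p = 0.00162; adjusted p = 0.110 with an estimated correlation), and 2 of 4 members rose, Krt28 and Krt25, or 3 adjusted over the list alone. Matrix and hair shaft genes rose (adjusted p = 0.000992; adjusted p = 0.138 with an estimated correlation), with 1 of 6 members past the test, the hair keratin Krt35, and 3 adjusted over the list alone. Companion layer genes rose (adjusted p = 0.00283; adjusted p = 0.125 with an estimated correlation), with 0 of 4 members past limma over all genes and 3 adjusted over the list alone. Among these, Krt17 was at 3.65 TPM at E11.5 and 810 TPM at E17.0.

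Basal epidermis genes, which also define the epithelial-like cells, rose as a list (adjusted p = 5.09e-05; adjusted p = 0.138 with an estimated correlation), with 1 of 12 members, Itgb4, rising and 6 when adjusted over the list alone. Upper follicle and sebaceous gland genes rose (adjusted p = 0.0205; adjusted p = 0.232 with an estimated correlation), with 0 of 8 members past limma and 2 adjusted over the list alone. Notch pathway genes rose (adjusted p = 0.00387; adjusted p = 0.188 with an estimated correlation), with 1 of 10 members, the ligand Dll1, rising and 2 when adjusted over the list alone. Heterochronic and fetal growth genes fell as a list (adjusted p = 5.09e-05; adjusted p = 0.0809 with an estimated correlation). Igf2 and Mest were the 2 of 11 members that fell over all genes, and 7 fell when adjusted over the list alone. Hmga2 of this list was at 132 TPM at E11.5 and 15.8 TPM at E17.0 (adjusted p = 0.0892). By camera the S phase list, genes of DNA replication, fell (adjusted p = 5.09e-05, or 0.495 with an estimated correlation). So did the G2/M list of mitosis genes (adjusted p = 0.0308, or 0.729 with an estimated correlation). Each had 0 of 15 members past limma over all genes or over the list alone. Neither passed fry (adjusted p = 0.175 and 0.542). Their scores did not pass the exact permutation test against day (r = -0.686, adjusted p = 0.206, and r = -0.385, adjusted p = 0.533). The Notch pathway and upper follicle lists did not pass fry either (adjusted p = 0.0585 and 0.0789), while 6 of the 10 lists did.

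The other lists did not pass camera, which tests for a shared direction and gave the list p-values below. Fry's mixed test is open to members moving both ways. By it the basement membrane (adjusted p = 1.67e-05), placode (0.00222), simple epithelium (0.00586) and kinase inhibitor lists (0.00806) passed. So did the suprabasal (0.0262) and dissociation stress lists (0.0283), while the Wnt, hedgehog, BMP and histone lists did not (lowest 0.447). Of the placode signals, 1 of 12 members rose, Trps1, and 2 rose and 1 fell when adjusted over the list alone (list adjusted p = 0.970). Foxi3 of that list was highest at E12.0, at 28.9 TPM, and was at 0.468 TPM at E17.0. None of the 12 Wnt targets, 3 hedgehog targets, 7 BMP targets and 12 replication-dependent histone genes passed limma, over all genes or over the list alone, and the list adjusted p-values were 0.970, 0.803, 0.803 and 0.803. Suprabasal differentiation genes had 1 of 7 members rising, Calml3, over all genes and over the list alone (list adjusted p = 0.0683). Of this list, Krt1, a keratin of differentiating epidermis, was highest at E13.5, at 92.6 TPM. Simple epithelium and periderm genes had 1 of 6 falling, Cldn6, and 1 rising and 2 falling when adjusted over the list alone (0.385). Of the kinase inhibitors, 1 of 4 fell, Cdkn1c, and 1 rose and 1 fell when adjusted over the list alone (0.803). Basement membrane genes had 1 of 14 rising, Egfl6, and 1 falling, Fras1, against 1 and 2 when adjusted over the list alone (0.388). Dissociation stress genes had 1 of 10 rising, Junb, over all genes and over the list alone (0.0721).

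Markers of other cell types were also followed in epithelial-like cells. Of the fibroblast markers, 2 of 5 tested rose, Col1a1 and Col1a2, and the only melanocyte marker tested, Mitf, rose as well, with the same counts when adjusted over the list alone. None of the markers tested for dermal papilla (1), endothelial (1), Merkel (2), immune (2), erythroid (1), nerve and Schwann (2) and skeletal muscle cells (1) passed limma over all genes. Adjusted over the list alone, 1 dermal papilla and 1 nerve and Schwann marker fell. Over all cells, 0 members of any of the 29 lists passed, while camera called the hair follicle stem cell, matrix, inner root sheath, companion layer, upper follicle, basal epidermis and dissociation stress lists higher with day and the S phase, G2/M and heterochronic lists lower. Their adjusted p-values ran from 1.68e-10 for S phase to 0.00490 for upper follicle genes, and with an estimated correlation none of the 10 passed (adjusted p = 0.122 with an estimated correlation for the heterochronic list, the lowest). Adjusted over the list alone, 13 of 15 S phase genes fell, 10 of 17 stem cell genes rose, and 5 of 6 melanocyte markers rose over all cells.

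**Figure D3:**
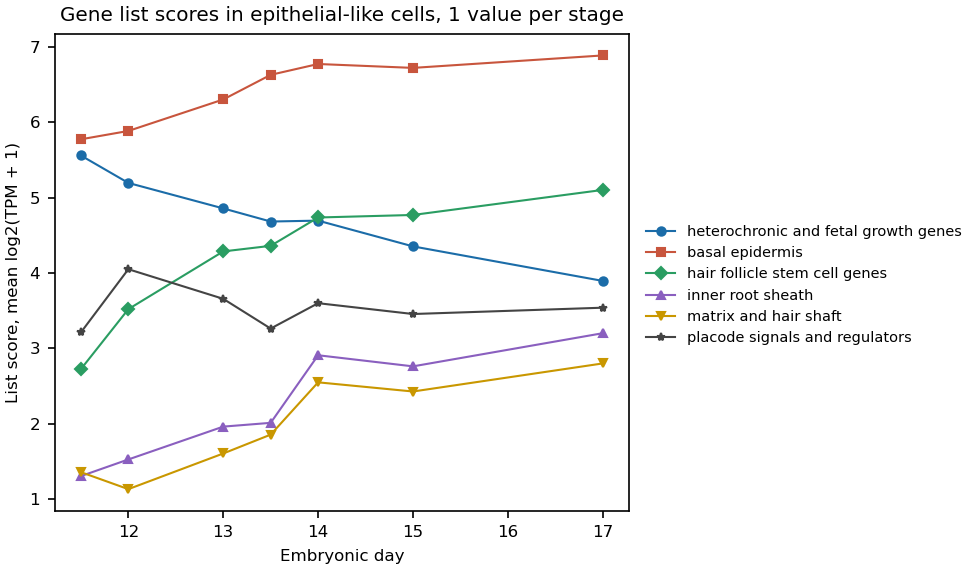
List score, the mean over members of log2(stage mean TPM + 1), against embryonic day in epithelial-like cells, with 1 point per stage (n = 1 sample, no error shown) for 6 of the 20 lists. Stem cell, basal epidermis, matrix and inner root sheath scores are higher at E17.0 than at E11.5, and the heterochronic score is lower.

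List scores were then related to embryonic day by exact permutation over all orders of the 7 stages, two-sided, as a family of 20 lists. In epithelial-like cells the heterochronic score fell with day (r = -0.981, exact p = 0.000397, adjusted p = 0.00794, and rho = -0.964, exact p = 0.00278). Its r was -0.982 without the 2 stages farthest from the median day. The inner root sheath score rose (r = 0.930, exact p = 0.00139; rho = 0.964, exact p = 0.00278; adjusted p = 0.0119; 0.893 without the farthest 2), as did the matrix score (r = 0.915, exact p = 0.00179; rho = 0.929, exact p = 0.00675; adjusted p = 0.0119; 0.920 without them). The basal epidermis score rose (r = 0.882, exact p = 0.00536; rho = 0.964, exact p = 0.00278; adjusted p = 0.0268; 0.898 without them), and so did the stem cell score (r = 0.884, exact p = 0.00754; rho = 1, exact p = 0.000397; adjusted p = 0.0302; 0.931 without them). Over all cells, 6 of 20 lists passed, namely the heterochronic (r = -0.959, exact permutation adjusted p = 0.0198), inner root sheath (0.942; 0.0298), stem cell (0.889; 0.0317), companion layer (0.881; 0.0357), matrix (0.849; 0.0364) and kinase inhibitor lists (0.856; 0.0364). By rho, 6 of 20 lists passed over all cells and 7 of 20 in epithelial-like cells. Over all cells the dissociation stress list, a sign of sample quality, passed by rho (0.929, exact permutation adjusted p = 0.0337). The matrix list did not (adjusted p = 0.0595). In epithelial-like cells the Notch pathway and companion layer lists passed by rho but not by r. Without E11.5, which had its own gate, the exact test of the other 6 stages gave 1 of 20 lists by r and 0 by rho over all cells, and 0 by r and 7 by rho in epithelial-like cells. The orders of 6 stages give no rho a p below 0.00278, or 0.0556 when adjusted for a single list. The loss of a call by rho alone thus does not show a weaker relation. By r a single list can pass, as the heterochronic list did over all cells (exact p = 0.00139, exact permutation adjusted p = 0.0278). This limit of rho therefore does not account for the calls lost by r. In epithelial-like cells r without E11.5 was -0.993 for the heterochronic score, 0.903 for the inner root sheath, 0.899 for the matrix, 0.836 for the basal epidermis and 0.906 for the stem cell score, and over all cells the heterochronic score had r = -0.991 and rho = -1. The lane format covers 5 stages, under the 6 required here for a correlation, so no r within 1 format is given.

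E12.0 and E17.0 were sorted by the same gate and have 3 plates each, so their epithelial-like cells were set side by side. Krt17 was at 6.85 TPM at E12.0 and 810 TPM at E17.0 (log2 fold 6.69), Krtdap, a secreted protein of stratifying keratinocytes, at 1.70 and 157 TPM (5.87), and Nfatc1 at 5.32 and 223 TPM (5.15). Lmcd1, Cd44, S100a14, Vdr (5.49, but 4.90 without E17.0 plate 3) and Stfa3 (5.10, but 4.30 without E17.0 plate 2) were the other 5 of the 8 with the largest folds toward E17.0. Foxi3 was at 28.9 and 0.468 TPM (-4.35), Rimklb at 42.95 and 0.975 TPM (-4.48), and Grb10 at 247 and 17.4 TPM (-3.75). Xist, Itgam, Pygm, Susd4 and Mpped1 were the other 5 of the 8 with the largest folds toward E12.0, and the Xist values go with the sex mix of the plates. All 16 genes were chosen for plate ranges that do not overlap, and with 1 sample per stage no test applies.

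The steps between neighbouring stages were also measured in epithelial-like cells. From E11.5 to E12.0, across the change of gate, Lhx2 went from 0.504 to 47.8 TPM (log2 fold 5.02), while Msx1, a homeobox target of BMP signals, went from 35.8 to 2.39 TPM (-3.44) and Igfbp2 from 593 to 85.9 TPM (-2.77). From E12.0 to E13.0, Krt17 went from 6.85 to 578 TPM (6.20) and Krt79 from 0.0647 to 75.8 TPM (6.17). From E13.0 to E13.5, Igfbp3, a binding protein of insulin-like growth factors, went from 1.64 to 60.7 TPM (4.54), and from E13.5 to E14.0 Dlx3, a homeobox gene of the hair matrix, went from 2.78 to 22.5 TPM (2.64) while Krt79 went from 111 to 27.8 TPM (-1.95; -0.91 without E13.5 plate 2). From E14.0 to E15.0, Hspa1a, a heat shock chaperone induced by stress, went from 9.88 to 408 TPM (5.23), with E15.0 plate means from 22.5 to 1543 TPM and a log2 fold of 1.498 without plate 1, and Wnt3 went from 25.5 to 7.17 TPM (-1.70). From E15.0 to E17.0, Dcn, the matrix proteoglycan decorin, went from 8.19 to 69.7 TPM (2.94; 3.64 without E15.0 plate 3) and Krt10, a keratin of differentiating epidermis, from 49.03 to 3.40 TPM (-3.51; -2.40 without E15.0 plate 4). These folds have no test, and E15.0 plate 1 enters the E15.0 mean with 9 epithelial-like cells.

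The third question concerned Sox9, Shh and Lrig1, which mark the edge of the placode and later stem cells, the centre of the placode and later matrix, and the upper follicle. Sox9 spans 112782224 to 112787760 on chromosome 11 of the mm10 build, Shh 28456815 to 28467256 on chromosome 5 and Lrig1 94604529 to 94700158 on chromosome 6, all annotated as protein-coding genes. Sox9 at 10 TPM or more was found in 1.79% of 56 epithelial-like cells at E11.5, 33.6% of 268 at E12.0 (exact binomial 95% interval 27.95 to 39.6%), 77.4% at E13.0, 90.9% of 154 at E13.5 (85.2 to 94.9%) and 72.1% at E17.0 (64.6 to 78.8%). Fibroblast-like cells were set beside them, although mean Lrig1 was 70.1 TPM there against 58.7 TPM in epithelial-like cells, so they give no background level for Lrig1. In fibroblast-like cells Sox9 was at 10 TPM or more in 28.9% of 439 cells, from 15.9% at E13.0 to 68.6% at E17.0, where the difference from epithelial-like cells was within counting error. Shh was found in 24.3% of epithelial-like cells at E12.0 (19.2 to 29.8%), 3.25% at E13.5 (1.06 to 7.41%) and 13.9% at E17.0 (9.05 to 20.2%), against 0 of 214 fibroblast-like cells at E13.0, which allows up to 1.40%, and 0 of 51 at E17.0, which allows up to 5.88%. Lrig1 was found in 53.6% of epithelial-like cells at E11.5, 96.2% at E13.0 and 76.4% at E17.0 (69.1 to 82.6%), and in 79.7% of all fibroblast-like cells, from 11.8% at E11.5 to 92.99% at E13.0. These shares depend on the threshold. At 1 TPM, Sox9 was found in 46.4% of epithelial-like cells at E11.5 and 82.5% at E12.0 and in 61.7% of fibroblast-like cells at E13.0, Shh in 8.44% of epithelial-like cells at E13.5, and Lrig1 in 83.9% of epithelial-like and 58.8% of fibroblast-like cells at E11.5. Median detection was 17603 genes per cell in epithelial-like and 18031 in fibroblast-like cells at E13.0, and 16546 and 17342 at E17.0. Nfatc1 went from 0 of 56 cells at E11.5, which allows up to 5.36%, through 11.6% at E12.0 to 68.5% at E17.0, where it was found in 45.1% of fibroblast-like cells, and Tbx1 went from 0.373% at E12.0 to 75.8% at E17.0, against 0 of 51 fibroblast-like cells at E17.0 (up to 5.88%). At 1 TPM, Nfatc1 was found in 65.3% and Tbx1 in 35.1% of epithelial-like cells at E12.0, and Nfatc1 in 74.5% of fibroblast-like cells at E17.0.

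**Figure D4:**
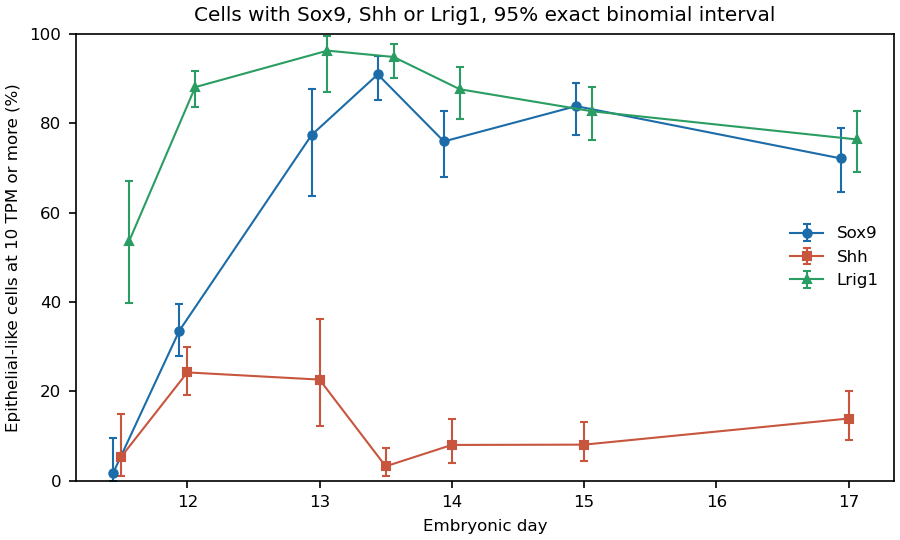
Share of epithelial-like cells (%) with Sox9, Shh or Lrig1 at 10 TPM or more against embryonic day, with exact binomial 95% intervals that cover counting error only. Sox9 goes from 1.79% at E11.5 to 90.9% at E13.5, and Shh from 24.3% at E12.0 to 3.25% at E13.5.

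Genes that vary with Sox9 from cell to cell were sought within each plate, by Spearman correlation given the number of genes detected, and tested with limma over the 7 stages. In epithelial-like cells Sox9 went together with Barx2, a homeobox gene (mean Fisher z 0.61, SE 0.089, adjusted p = 0.00167), Prdm1, a transcriptional repressor of upper follicle cells (0.54, adjusted p = 0.00230), Pthlh, the parathyroid hormone-related peptide (0.48, adjusted p = 0.00122), and Nfatc1 (0.41, adjusted p = 0.00398). Fgf9, Elmo1, Tanc2, Trpv6, Ppp1r14c and Itgb8 were the other 6 of the 10 strongest. Tnfrsf19, a Wnt target and receptor also called Troy (-0.42, adjusted p = 0.00153), Wnt3 (-0.38, adjusted p = 0.00153) and Bmp2, a placode ligand (-0.32, adjusted p = 0.0108), went against Sox9. In all, 641 genes went with Sox9 and 438 against it, of 28072 tested (5421 at an unadjusted p under 0.05). These 1079 genes became 423 without the term for detected genes and 586 with a cell cycle term. Of 16 stem cell genes 6 went with Sox9 and 1 against it, or 11 and 2 adjusted over the list alone, and with it went Lgr5 (0.37), Tbx1 (0.36) and Runx1 (0.32). Of 12 placode genes 2 went with Sox9 and 4 against it, or 3 and 6 adjusted over the list alone, and of 12 Wnt targets 1 and 3, or 1 and 5, with Lef1 at -0.30 and Axin2 at -0.28. Of the S phase and G2/M genes 2 each went against Sox9, or 10 each adjusted over the list alone.

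Over all cells, as planned, 295 genes went with Sox9 and 102 against it, of 28483 tested (5174 unadjusted), and these 397 became 157 without the term for detected genes and 790 with a cell cycle term. Barx2 (0.59, adjusted p = 0.0263), Ppp1r14c (0.51, adjusted p = 0.0123), Itgb8, an integrin chain (0.50, adjusted p = 0.00536), and Lgr4, a receptor of Wnt-enhancing R-spondins (0.44, adjusted p = 0.0418), were among the 10 strongest with it, and Lef1, a transcription factor of Wnt signalling (-0.26, adjusted p = 0.0384), and Dcn (-0.27, adjusted p = 0.0221) among those against it. These correlations run over epithelial-like and fibroblast-like cells together and can also reflect their mix. Median Lef1 was 283 TPM in fibroblast-like and 30.9 TPM in epithelial-like cells, and median Sox9 was 2.96 and 25.8 TPM. Of 8 fibroblast markers 2 went against Sox9. Lef1 and Dcn also went against Sox9 in epithelial-like cells alone. The Sox9 counts rest on single stages. Over all cells, limma called 2505 genes without E11.5, 149 without E13.0, 15 without E13.5, 0 without E14.0 (3580 at an unadjusted p under 0.05), 20 without E15.0 and 61 without E17.0. In epithelial-like cells it called 1814 without E11.5, 712 without E13.0, 513 without E13.5, 131 without E14.0, 198 without E15.0 and 333 without E17.0.

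Shh went together with genes of Wnt and placode signalling in epithelial-like cells. Notum, a Wnt-removing enzyme induced by Wnt (mean z 0.47, SE 0.078, limma adjusted p = 0.0192), Nkd1, a Wnt feedback inhibitor (0.45, adjusted p = 0.0177), Edar, the ectodysplasin receptor (0.41, adjusted p = 0.0192), Bmp2 (0.39, adjusted p = 0.0462) and Lef1 (0.36, adjusted p = 0.0292) were higher in cells with more Shh. Gas1, a co-receptor for Shh (-0.45, adjusted p = 0.0192), Krt15 (-0.39, adjusted p = 0.0249), Barx2 (-0.38, adjusted p = 0.0192), Sostdc1, a BMP and Wnt inhibitor (-0.36, adjusted p = 0.0192), and the imprinted RNA H19 (-0.46, adjusted p = 0.0192) went against it. In all, 68 genes went with Shh and 63 against it (2955 unadjusted), and the 131 became 486 with Pearson correlation. All 20 named genes had the same sign in each of the 7 stages. They were chosen for their mean z over these stages, so the shared sign is no independent evidence. The E13.0 value came from plate 1 alone (23 cells, 7 with Shh). Of 12 Wnt targets 6 went with Shh and 0 against it in limma, or 10 and 0 adjusted over the list alone. Of 11 placode genes 4 and 1 did, or 8 and 1, and of 17 stem cell genes 0 and 2, or 0 and 6, adjusted over the list alone. Of 12 heterochronic genes 2 went against Shh, or 8 adjusted over the list alone, and of 12 basal genes 1, or 5.

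Over all cells, 252 genes went with Shh and 157 against it (3466 unadjusted), led by Edar (0.33, limma adjusted p = 0.00850), Ascl4 (0.30, adjusted p = 0.0150), Cdh3, the placental cadherin of placodes (0.30, adjusted p = 0.00563), and Wnt10b, a Wnt ligand of placodes (0.29, adjusted p = 0.00563). Gas1 (-0.30, adjusted p = 0.00807) and Slc12a2, an ion transporter (-0.29, adjusted p = 0.00768), led those against it. Here too the correlations run over both classes of cells and can reflect their mix. Shh was at 10 TPM or more in 13.2% of epithelial-like and 0% of fibroblast-like cells. The 409 genes became 253 without the term for detected genes and 847 with Pearson correlation. Over all cells, limma called 783 genes without E12.0, 79 without E13.0, 119 without E14.0, 75 without E15.0 and 126 without E17.0. In epithelial-like cells it called 1 without E12.0, 200 without E13.0, 0 without E14.0 (2339 at an unadjusted p under 0.05), 0 without E15.0 (2474 unadjusted) and 0 without E17.0 (2402 unadjusted).

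**Figure D5:**
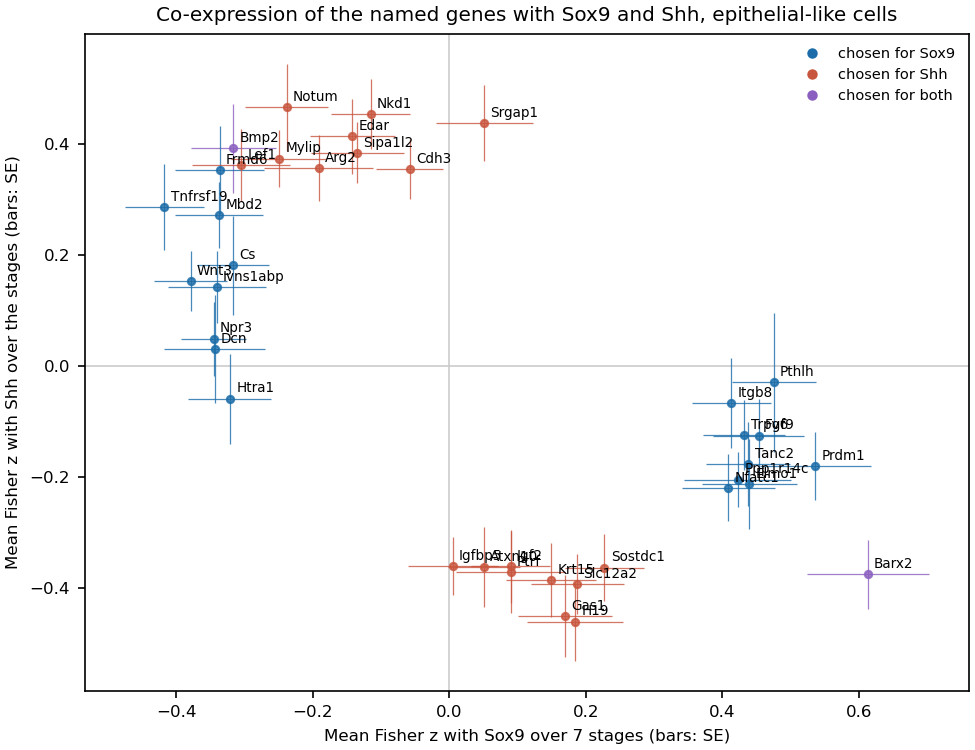
Mean Fisher z over 7 stages of each gene's correlation with Sox9 (x axis) and with Shh (y axis) in epithelial-like cells, for the named genes, coloured by the gene they were chosen for; bars are SE over the stages. Barx2 lies at 0.61 with Sox9 and -0.38 with Shh, and Bmp2 at -0.32 and 0.39.

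Lrig1 went together with basal epidermis genes in epithelial-like cells. Krt5 (mean z 0.39, SE 0.040, limma adjusted p = 0.000136), Krt15 (0.38, adjusted p = 0.00537), Sema3f, a guidance ligand (0.41, adjusted p = 0.000136), and Dst, a linker of hemidesmosomes (0.35, adjusted p = 0.00580), were higher with Lrig1. Nrp2, a semaphorin receptor (-0.43, adjusted p = 0.000136), Cux1, a homeobox gene of the inner root sheath (-0.37, adjusted p = 0.000198), Msx1 (-0.30, adjusted p = 0.00537), Msx2, a matrix homeobox gene (-0.29, adjusted p = 0.0295), and Bmp4 (-0.28, adjusted p = 0.0165) went against it. In all, 198 genes went with Lrig1 and 72 against it (3565 unadjusted), and these 270 became 166 with a cell cycle term and 499 with Pearson correlation. Of 12 basal epidermis genes 4 went with Lrig1 and 0 against it in limma, or 10 and 0 adjusted over the list alone, and of 7 BMP targets 0 and 3, or 0 and 5. Of 10 dissociation stress genes 0 went with Lrig1 over all genes, but 6 when adjusted over the list alone, and over all cells these were 3 and 7. Over all cells, 258 genes went with Lrig1 and 76 against it (3595 unadjusted), led by Vgll3, a transcriptional cofactor (0.43, adjusted p = 5.87e-05), and S100a11 (0.40, adjusted p = 0.000721). As for Sox9, correlations over all cells run over both classes of cells and can also reflect their mix. Over all cells, the count was 723 without E11.5, 217 without E13.0, 138 without E13.5, 70 without E14.0, 149 without E15.0 and 206 without E17.0. In epithelial-like cells it was 451 without E11.5, 140 without E13.5, 67 without E14.0, 58 without E15.0 and 141 without E17.0.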

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

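The tests of other stage orders and sign patterns, of mixed-in fibroblast-like cells, of the position of the epithelial-like cells on E15.0 plate 1, of a batch effect of 1 plate and of shared numbers in the plate names were chosen only after the results were seen.

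E15.0 plate 1 lay far from the other 3 plates of its stage in 11 of 25 measures. Chance flags about 1 in 20 groups of 4 values with equal spread. That rate does not carry over to the list scores, which rest on 9 epithelial-like cells of plate 1 against 51 to 57 on the others. Shares of epithelial-like and fibroblast-like cells also depend on each other. E15.0 plate 1 had 10% epithelial-like cells (59.3 to 66.3% on the others), 82.2% fibroblast-like cells (20.5 to 26.7%) and Xist at 1 TPM or more in 2.22% of cells (54.7 to 58.1%). In its 9 epithelial-like cells the list score was 2.56 for placode genes (3.51 to 3.61 on the others), 3.48 for Wnt targets (4.23 to 4.38), 4.03 for hedgehog targets (4.84 to 4.996) and 2.90 for BMP targets (4.21 to 4.32). The stem cell score was 4.46 (4.80 to 4.82), the basal epidermis score 6.31 (6.78 to 6.86), the basement membrane score 4.01 (4.12 to 4.13) and the dissociation stress score 7.85 (5.55 to 5.80).

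The first pattern weighed is the excess of fibroblast-like cells on E15.0 plate 1 and the E13.0 plates. A wrong stage label for E15.0 plate 1 is argued against by its epithelial-like cells, whose genes with a trend lay at a median position of 0.920 between the E13.0 mean (0) and the mean of the other E15.0 plates (1), although its fibroblast-like cells do not part the stages, with mean correlations that differed by 0.00255. An effect on 1 plate alone is argued against for E13.0, where the lowest share was 73.3%. A looser gate on ITGA6 may account for both, since the median of Itga6 mRNA in fibroblast-like cells of E15.0 plate 1 was 27.1% of the lowest other plate of that stage (9.31 against 34.3 TPM), and that of the highest E13.0 plate was 46.2% of the lowest (11 cells) of 7 plates of E14.0, E15.0 (2 to 4) and E17.0 with 10 or more such cells. These 4 plates share 4 digits in their names, which may be a month and day (E15.0 plates 2 to 4 and the E17.0 plates share others), and have shares at least 46.5 percentage points above the other 14, but the full number of E15.0 plate 1 is that of 1 E13.0 plate only, and the lowest share on the 2 E13.0 plates with another number was 82.4%, so whether a batch is shared is not known and a difference in whisker tissue stays open and untested.

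The second pattern is the set of 503 genes with a trend in epithelial-like cells. The sex mix is argued against as the whole cause, since 100% of the 503 genes kept their sign and an unadjusted p under 0.05 in cells with Xist under 1 TPM. These cells are part of those the genes were chosen in, and at the adjusted threshold 375 of the 503 passed there. At E15.0, 2 description formats could be compared, the lane format and a later format that all E17.0 plates have. An effect that follows these 2 formats is argued against there. The difference between them was -0.824% of the change from E12.0 to E17.0 at the median (upper quartile 10.9%, 1 plate against 2). Another format, on E11.5, E12.0 plates 2 and 3 and E13.0 plates 2 and 3, has no plate at E15.0, so its effect could not be tested there. The formats thus run in part with embryonic day. The slope within the lane format was 114.3% of that over all plates, but the 503 genes were chosen with these plates included. That format has no plate of E11.5 or E17.0, so it cannot test the format at those stages. No label says that the format marks a sequencing batch, so a batch effect stays open. With the number of detected genes as a covariate the median slope kept 98.5% of its size, but its median SE went from 0.060 to 0.071 log2 per day and with 1 degree of freedom less 32 genes passed. The E11.5 gate is argued against as the whole cause. From E12.0 to E17.0, which had the same gate, the 503 genes changed by a median of 1.94 log2 in the direction of the trend. These genes were chosen with both stages included, and without E11.5 111 genes passed, 95 of them among the 503. A hypothesis that these trends are developmental may be kept on these tests. A part of the E11.5 gate in the trends, the 1 sample per stage and an untested shift in the mix of epithelial cell types stay open.

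The third pattern is the lack of trend calls over all cells. Removing the 453 cells with 3 or more fibroblast markers gave 268 calls, 181 of them rising. That these calls came through the smaller number of cells alone is argued against. Removing as many random cells from each plate gave a median of 0 calls (highest 25 in 10 draws). Epithelial-like cells are fewer still, and no draw matched their number. Mixing of fibroblast-like cells into the stage means may thus hide trends, as a hypothesis made and tested on the same data. It is not the only choice the lack of calls depends on, since with every cell kept the rank of the stage gave 434 calls and a pseudocount of 5 TPM gave 70.

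The limit for a count of 0 is 3 of 1614 cells (0.186%), and it gives no background rate for the rule of 3 or more markers. By that rule there were 46 with endothelial, 56 with nerve and Schwann, 27 with erythroid, 14 with melanocyte, 12 with Merkel cell and 10 with immune markers.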

How the results depend on the processing

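Fits in epithelial-like cells, their alternatives, steps without 1 plate, the check of same-numbered plates and rescaling to protein-coding genes were chosen after the data were seen; the cause of each difference was not tested unless named. No paired analysis was possible because the replicate numbers only number cells and each stage is 1 sample. E15.0 plates 2 to 4 carry the same numbers in their names as E17.0 plates 1 to 3, and E13.0 plate 1 the same as E15.0 plate 1, but what the numbers stand for is not stated. Deviations of the 3 same-numbered E15.0 and E17.0 plates from the mean of the 3 at each stage had correlations of -0.106 to 0.0720 over all cells and -0.0355 to 0.0178 in epithelial-like cells, and 1 of 3 E15.0 plates was closest to its own number in each, which gives no sign of pairing. The 0 trend calls over all cells became 70 with a pseudocount of 5 TPM, 13 with the mean of log2 values, 30 with protein-coding genes rescaled, 434 with the rank of the stage and 503 in epithelial-like cells, with 0 to 62 when 1 stage or plate was left out. The 503 epithelial calls became 1441 with the rank of the stage (479 shared) and ranged from 44 to 562 when 1 stage or plate was left out. Curvature calls went from 0 over all cells to 1 in epithelial-like cells, and that 1 became 3 with protein-coding genes rescaled and 0 with the mean of log2 values, with 0 to 2 under leave-one-out.

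The 397 genes called with Sox9 over all cells became 157 without the term for detected genes, 790 with a cell cycle term and 1079 in epithelial-like cells, with 0 to 2505 under leave-one-out. The 1079 became 423 without that term and 586 with a cell cycle term, with 131 to 1814 under leave-one-out. The 409 genes called with Shh became 253 without the term, 847 with Pearson correlation and 131 in epithelial-like cells, with 75 to 783 under leave-one-out, and the 131 became 486 with Pearson correlation, with 0 to 200 under leave-one-out. The 334 genes called with Lrig1 ranged from 70 to 723 under leave-one-out, and the 270 in epithelial-like cells became 166 with a cell cycle term and 499 with Pearson correlation, with 58 to 451 under leave-one-out. Shh with at least 15 expressing cells per plate left under 3 stages and was not run. The 10 lists called over all cells became 6 with a filter at 10 TPM, and the 10 in epithelial-like cells became 6 with fry; with an estimated correlation both became 0. Lists related to day went from 6 to 1 over all cells and from 5 to 0 in epithelial-like cells by r without E11.5. By rho they went from 6 to 0 and stayed at 7. With 6 stages a single list cannot pass by rho, so the loss of a call by rho alone does not show a weaker relation. By r a single list can pass. The heterochronic score lost its call by r in epithelial-like cells with r at -0.993.

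No named gene reversed. Of 646 comparisons of named epithelial trends, 549 kept their call and 97 lost it; for named co-expression these were 520 and 120 of 640 in epithelial-like cells and 568 and 130 of 698 over all cells. Of 208 folds between E12.0 and E17.0, 207 stayed within the plate spread, as did 489 of 496 for steps between neighbouring stages without 1 plate. Leaving out some plate moved the fold by more than 1.5-fold for 10 of 48 named steps over all cells and 16 of 48 in epithelial-like cells, and E15.0 plate 1 did so for 6 in each. Shares at 1 TPM and 10 TPM differed beyond the counting interval in 385 of 456 cases, so a share holds only for its threshold. The unknown depth limits shares near 0 and the Shh counts, which rest on few cells per plate.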

Other observations

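The test of the difference between the Shh and Sox9 correlations and the counts under other stage orders and sign patterns were chosen only after the results were seen.

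Fibroblast-like cells were followed in the 5 stages with at least 17 of them. Mean Col1a1, which helps define them, was 293 TPM at E11.5 and 2488 TPM at E17.0, while Hmga2 was 142 TPM at E11.5, 45.2 at E13.0 and 6.503 at E17.0, and Igf2bp1, an RNA-binding protein of fetal growth, was 84.5 and 22.6 TPM at the ends. Igf2 was 30.4 TPM at E11.5 and 480 TPM at E17.0 in these cells, while in epithelial-like cells it went from 626 to 19.2 TPM; the difference between the classes was not tested. Tbx18, a gene of the dermal condensate, was 1.68 TPM at E11.5, 130 TPM at E13.0 and 32.6 TPM at E17.0, and Sox2, which marks dermal papilla cells, was 2.31 TPM at E11.5 and 52.04 TPM at E17.0. Ptch1, a receptor and target of hedgehog signals, was 47.8 TPM at E11.5 and 240 TPM at E13.0. These are single values per stage, from 17 cells at E11.5, 214 at E13.0 and 51 at E17.0.

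Correlations with Shh and with Sox9 in epithelial-like cells were compared directly, by a limma test of their difference over the 7 stages. The plates were not the same for both genes. Sox9 values used every plate, while Shh values at E13.0 came from plate 1 alone (23 cells, 7 with Shh) and left out E15.0 plate 1. Differences between plates thus enter the comparison at these stages. Of 28071 genes, 134 went more with Shh and 233 more with Sox9 (4813 at an unadjusted p under 0.05). Bmp2 (difference in z 0.71, adjusted p = 0.0115), Notum (0.70, adjusted p = 0.0139), Tnfrsf19 (0.70, adjusted p = 0.0127) and Lef1 (0.67, adjusted p = 0.0115) went more with Shh in 7 of 7 stages. Barx2 (-0.99, adjusted p = 0.0115) and Gas1 (-0.62, adjusted p = 0.0167) went more with Sox9 in every stage, as did Prdm1 (-0.72, adjusted p = 0.0184) and Nfatc1 (-0.63, adjusted p = 0.0164) in all but 1.

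Erythroid markers were found in 27 cells, of which 12 came from E13.5 plate 1, 13 from E14.0 plate 1 and 2 from E15.0 plate 2, with 0 on the other plates of E13.5 and E14.0. Of the 27, 19 were also epithelial-like by their markers. At E11.5 the 17 cells with nerve and Schwann markers were all from the 1 plate of that stage.

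Stage days were reassigned in 100 orders, the real one included. In epithelial-like cells 1 of the 100 orders reached the real count of linear trends, the real order itself (503 against 7 in the highest other). This argues against a chance order of the stages for that count. However, 1 of 100 is the lowest share these orders can give, and the selection of these cells followed a look at the data. With 1 sample per stage, the orders cannot tell age from other differences between samples that run with it. Over all cells the real order gave 0 linear trends (highest other 1) and 0 curvature calls (highest other 1248), so that 100 of 100 orders reach each by definition and nothing about chance can be read from them. For curvature in epithelial-like cells chance cannot be excluded (5 of 100; real 1, highest other 2075). Orders with so many curvature calls point to a structure among the stages, such as a group of them that differs, which was not tested further. Signs of the stage correlations were flipped in 64 patterns, and the limit of 3 of 64 was set after the results were seen. Sox9 over all cells lay at that limit (3 of 64, real 397, highest other 1958) and gave 0 calls without E14.0, so chance is not excluded there. In epithelial-like cells no other pattern reached the Sox9 count (1 of 64, real 1079, highest other 857). The same held for Shh over all cells (409 against 30 in the highest other) and in epithelial-like cells (131 against 1). It also held for Lrig1 over all cells (334 against 216) and in epithelial-like cells (270 against 113). These results argue against chance for each count taken alone. However, 1 of 64 is the lowest share these patterns can give, and the counts were not adjusted for one another. The Shh count in epithelial-like cells was also 0 without E14.0, E15.0 or E17.0. The higher Sox9 pattern over all cells points to a stage whose correlations differ from the rest, and leaving out E11.5 gave 2505 calls.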
